A study of Glycine max with 8 samples.

How the data were processed

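Transcripts of developing soybean seeds (Glycine max, cultivar Tamahomare) were measured on 8 Affymetrix soybean arrays, 2 for each of 4 stages. The deposited values are linear signal intensities, 1 per probe set and array, in a single table of 61170 probe sets. MAS5, the Affymetrix summarisation program, is named in the submitters' processing notes for 4 samples, those of 5 mm and fully grown beans. For the other 4 samples the program is not given in the sources used here. Biotin-labelled cRNA was made from total RNA, per the labels' protocols. The scaling target, detection calls and program version are not given in the sources used here.

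The deposited intensities were not on a common scale. The median over tested probe sets lay between 24.1 and 138 on the 8 arrays, and the level of 9 bacterial and phage hybridization control probe sets (geometric mean) lay between 462 and 1032. On the scale log2(median + 16), the array medians of the samples for which MAS5 is named and of the other samples differed by 0.93 on average, and single arrays differed by up to 1.94. The plan, made before the data were examined, took the values as deposited and centred every array on its median only if medians differed by over 1 between these sets of samples. The limit was not reached on that scale, so the plan kept the values as deposited. Centring, planned as an alternative, was used for the results instead, a departure from the plan decided after the values were seen, because the arrays were not on a common scale. Without the added 16 the difference was 1.20, but this was computed later and played no part in the choice. The values as deposited were analysed as an alternative.

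The 37641 soybean probe sets were used for the comparisons. The array also carries 15864 probe sets of the oomycete Phytophthora sojae and 7530 of the nematode Heterodera glycines, which served as background, and 135 control probe sets, which were left out. A soybean probe set was tested when it exceeded the 95th percentile of the pathogen probe sets of the same array on at least 2 of 8 arrays. This left 33625 probe sets (89.3%), of which 45 were ribosomal RNA. Each array was scaled linearly to an equal median over these, and log2(scaled signal + 16) was analysed. Fold changes are on this scale, which understates the change of dim transcripts, and a ceiling on bright signals would do so too. A stage whose arrays both lay at or below the background percentile was taken as not above background, and a fold against it is given as "at least", the geometric mean of the brighter stage over that of the dim stage's background percentile, both scaled. The number of arrays limits the precision, and no depth applies to array signals.

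Group means were fitted to all 8 arrays together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), because 2 arrays per stage say little about the spread. The 3 successive steps of development were tested as contrasts, two-sided, with Benjamini-Hochberg adjustment over the 33625 probe sets and a threshold of 0.05. The labels do not say that replicates came from separate plants, so the p-values measure the spread between these samples, which may be technical. The fit was tested on simulated data with 200 changed probe sets among 33625. It recovered 93% of 2-fold changes for bean 2 mm against pod elongation, 93% for bean 5 mm against bean 2 mm and 90% for fully grown against bean 5 mm, and 100% of 4-fold changes for each, with 6, 6 and 2 false calls. The simulation gave all arrays of a probe set an equal spread and changed none of the dimmest probe sets. In the data, the median absolute log2 difference between replicates was 0.272 in fully grown beans, against 0.118 to 0.133 at the other stages. Far more probe sets were also called, so the simulation does not show how the fit copes with either.

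Gene symbols came from the platform's probe annotation, updated through RefSeq (assembly Glycine_max_v4.0, used only for names). It lists 9047 probe sets, 8677 of them with 1 gene and 370 with several. Of the former, 8652 matched RefSeq. The other 28594 soybean probe sets are unnamed here. The 8195 tested probe sets with 1 gene stood for 5814 genes, 953 of which have a symbol other than a locus number. No coordinates are given, since the build behind the array is not given in the sources used here. Named genes were fixed by rule: for each step, the 12 largest rises and 12 largest falls among called genes with a symbol whose arrays did not overlap between the stages, and up to 4 called members of each gene list with the largest change, with the brightest probe set standing for a gene. Genes outside this rule are said to be so where they appear.

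Gene lists were written before the data were examined, by symbol patterns and descriptions. The reference gave no descriptions, so members were found by symbol alone and lists are incomplete. Lists with at least 5 measured genes were tested with camera at an inter-gene correlation of 0.01, adjusted over 30 tests. They were tested again with an estimated correlation, a setting that gave larger p-values also where the estimate was close to 0.01. A further 14 families were listed after the symbols and the data had been seen, and their adjusted p-values do not allow for that choice. Alternatives were other pseudocounts (1 and 64), normalizations, filters and variance models, the replicate number as a block, and leaving out each array. A further filter left out probe sets whose identifiers end in _x_at, _s_at or _a_at. These are called cross-hybridizing below for short, although sets ending in _a_at may match several transcripts of 1 gene only. Normalization by the hybridization controls and 2 comparisons between stages with like control levels were added after the data were seen. The values as deposited were the planned form, and became an alternative when centring took their place. Figures were drawn with matplotlib 3.10.9.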

Results

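Transcript levels were followed through early soybean seed development at 4 stages: elongating pods, pods with beans of 2 mm, beans of 5 mm, and green, fully grown beans. Each stage had 2 arrays. The design text asks which transcripts change from stage to stage. Replicate arrays correlated across probe sets, which are not independent replicates, at r = 0.991 for pod elongation, 0.987 for bean 2 mm, 0.988 for bean 5 mm and 0.969 for fully grown beans. Among 33625 tested probe sets, 25792 (76.7%) differed among the stages (limma, adjusted over all tested probe sets).

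Stage, tissue and array set changed together. By the labels, pods were part of the pod elongation and bean 2 mm samples and not of the others. MAS5 is named for bean 5 mm and fully grown beans only, so the step from bean 2 mm to bean 5 mm crossed both labelled divisions. Across tested probe sets, however, bean 2 mm arrays correlated at 0.930 to 0.956 with bean 5 mm arrays and at 0.799 to 0.834 with pod elongation arrays. How much pod tissue the bean 2 mm samples held was not tested. The hybridization controls were at 462 on both pod elongation arrays, 838 and 839 at bean 2 mm, 475 and 482 at bean 5 mm, and 987 and 1032 in fully grown beans, so each step also crossed a difference in control level. Control level and stage cannot be told apart within a step. Changes are therefore given relative to the typical transcript of each array. The actin 3' to 5' signal ratio, a measure of RNA integrity, was 2.05 and 2.09 at pod elongation and 3.64 and 3.60 at bean 2 mm. It was 2.07 and 2.22 at bean 5 mm, and 2.73 and 4.80 in fully grown beans. This ratio split the stages as the control level did, so each step crossed a difference in it too.

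**Figure D1:**
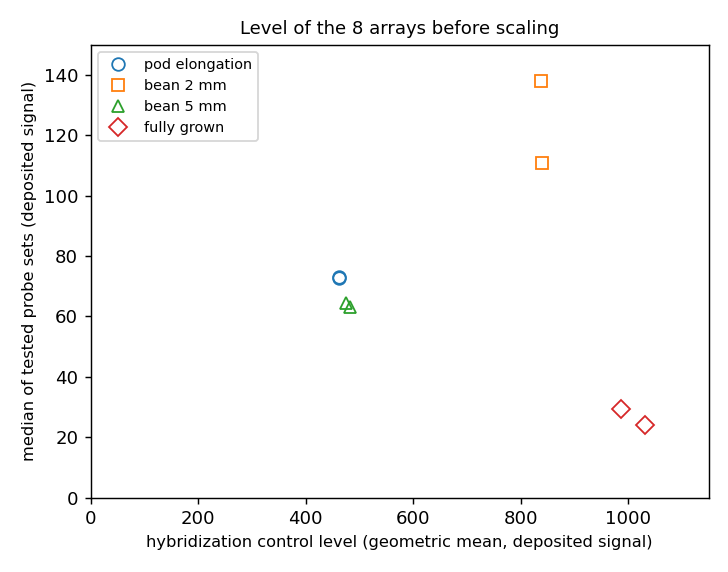
Median deposited signal of the tested probe sets (vertical axis) against the geometric mean signal of the hybridization controls (horizontal axis), 1 point per array, by stage. Fully grown arrays combine the highest control levels, 987 and 1032, with the lowest medians, 29.3 and 24.1.

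From pod elongation to bean 2 mm, ANR1, anthocyanidin reductase, rose from a scaled signal of 158 ± 19.0 (SD, n = 2, as for all later values) to 2418 ± 299, 14.0-fold higher. DFR1, dihydroflavonol reductase, rose 13.4-fold and ANS2, anthocyanidin synthase, 13.3-fold. The sugar transporter SWEET24 rose 34.4-fold, from 14.2 ± 4.88 to 1015 ± 25.4, and SCB1, a seed coat protein, rose 5.88-fold. HPS, the other seed coat marker found by symbol, fell 7.03-fold, from 140 ± 16.1 to 6.10 ± 1.35, with 1 bean 2 mm array below background. LEC1-A, a regulator of embryo maturation, rose at least 28.5-fold to 176 ± 51.8. SSTP-1 rose 178-fold, from 7.98 ± 0.733 to 4251 ± 368.

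Other transcripts fell in the same step. KTI-2, a Kunitz trypsin inhibitor, fell 44.6-fold, from 2348 ± 57.4 to 37.2 ± 6.64. The flavonol synthase FLS1 fell 15.7-fold and CHR5, chalcone reductase, at least 39.1-fold. The probe sets of KTI-2 and CHR5 are of the kind that can match several transcripts, so their falls may not be those of 1 gene alone. H4, the only core histone found by symbol, fell 15.5-fold, from 829 ± 16.8 to 39.2 ± 13.1, on a probe set of the kind that can match several transcripts. The identifier of this set shares its main number with that of VSPA, a vegetative storage protein. A fall of a histone transcript is therefore not established. Of 5 flower organ genes, AP1A and AG1, floral homeotic regulators, fell by 2.67 and 2.58 on the log2 scale, while AGL1L rose 3.32-fold and SEP1 1.65-fold. For AG1, 1 bean 2 mm array was below background. Of 25 phenylpropanoid and flavonoid genes 9 rose and 9 fell (9 and 11 adjusted over the list alone), and the list was not called, with adjusted p = 0.49 (camera).

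Of 6 measured photosynthesis genes 4 fell and 1 rose, with equal counts when adjusted over the list alone. The rise lost its call without pod elongation replicate 1 or 2 or bean 2 mm replicate 1. RCA14, a Rubisco activase, fell 4.12-fold and CAB3, a chlorophyll-binding protein, 2.81-fold, from 4671 ± 22.5 to 1685 ± 452. The probe set of CAB3 is of the kind that can match several transcripts. The other members that fell, RCAALPHA and RCABETA, are Rubisco activases like RCA14. The probe sets of RCA14 and RCAALPHA share the main number of their identifiers, so these falls may not be separate signals. The list gave adjusted p = 0.0508 and adjusted p = 0.543 with an estimated correlation, so it was not called. The adjusted p was 0.0486 without pod elongation replicate 2, 0.0299 without bean 2 mm replicate 1, 0.0477 without bean 5 mm replicate 1, and 0.0472 and 0.0468 without fully grown replicate 1 and 2. With all arrays it was 0.0391 at pseudocount 1, 0.0485 without the filter on dim probe sets, 0.0441 with the replicate block, 0.003 with the mean over all probe sets of a gene, 0.0209 as deposited and 0.0377 with scaling to the hybridization controls.

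Of 9 lipoxygenases, which oxidise unsaturated fatty acids, 3 fell (3 adjusted over the list alone), VLXC 7.93-fold and LOXB1 7.67-fold among them, against 6 lower with scaling to the hybridization controls and 3 lower and 1 higher as deposited. The probe sets of LOXB1 and VLXB, which also fell, share the main number of their identifiers. Both are of kinds that can match several transcripts. The list's adjusted p of 0.112 became 0.0472 and 0.0468 without fully grown replicate 1 and 2, 0.0406 with the mean over all probe sets of a gene and 0.0176 as deposited. Of 8 other seed proteins (6 protease inhibitors, P34 and a sucrose-binding protein) 4 fell and KTI3 rose, with equal counts when adjusted over the list alone and adjusted p = 0.121, against 0.00318 as deposited.

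In this step 15755 of 33625 probe sets changed, 8904 higher and 6851 lower, and 5639 changed at least 2-fold, 2251 of them higher. The share of calls that were higher was 56.5%, against 83.8% for the values as deposited, which called 24420, and 47.7% with scaling to the hybridization controls.

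From bean 2 mm to bean 5 mm, several seed protein and oil transcripts rose. HPS, a hydrophobic seed protein, rose 74.0-fold to 1640 ± 382, with 1 bean 2 mm array below background, and the inhibitor KTI3 36.0-fold, from 60.6 ± 22.9 to 2729 ± 708. FAD2-1A, a seed oleate desaturase, rose 20.3-fold, from 23.3 ± 0.362 to 812 ± 310. LEC1-A rose 3.86-fold to 712 ± 34.7 and WRI1B, a regulator of oil synthesis, 2.53-fold. CKX3, a cytokinin oxidase, fell 6.85-fold, from 682 ± 103 to 87.1 ± 26.8. MIPS4, an inositol phosphate synthase, fell 6.76-fold and AUX22, an auxin-response gene, 3.98-fold.

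Of 25 late embryogenesis abundant and seed maturation genes 13 rose (15 adjusted over the list alone), with adjusted p = 1.01e-06 (camera) and adjusted p = 0.543 with an estimated correlation. For the values as deposited 13 were higher and 6 lower. The member that fell, LEA-2, named after its values were seen, lost its call without any single array of the first 3 stages. Without bean 2 mm replicate 1 or 2, 8 members rose. PM30 rose 16.3-fold and PM34 10.7-fold, the latter with 1 bean 2 mm array below background. On the log2 scale the rise of PM30, 4.03, was 4.65 without bean 5 mm replicate 1 and 3.40 without replicate 2, and that of PM34, 3.42, was 4.17 and 2.67.

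Of 8 other seed proteins 4 rose (7 adjusted over the list alone), with adjusted p = 6.38e-06 and adjusted p = 0.543 with an estimated correlation. The number was 2 without bean 2 mm replicate 2 and 7 without bean 5 mm replicate 1. Of 13 fatty acid synthesis genes 6 rose (6 adjusted over the list alone), with adjusted p = 0.000535 and adjusted p = 0.283 with an estimated correlation, while for the values as deposited 2 were higher and 6 lower. Of these, 3 rose without pod elongation replicate 1 or 2, 2 without bean 2 mm replicate 2 and 1 without bean 5 mm replicate 2.

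The globulin list, 1 of whose 10 members is no storage protein by its symbol, had no called member, also when adjusted over the list alone, and adjusted p = 0.378, against 6.48e-06 as deposited, where 3 were higher and 2 lower. With scaling to the hybridization controls 3 were higher. Without bean 5 mm replicate 1 the adjusted p was 0.0206 and 3 members were higher, and without replicate 2 the number was 1. The 2 arrays of this stage differed for such transcripts. GY1, a glycinin chosen after its values were seen, was at 13.6 on replicate 1 and 548 on replicate 2, and D-II, a Bowman-Birk inhibitor outside that list, at 122 and 1073.

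**Figure D2:**
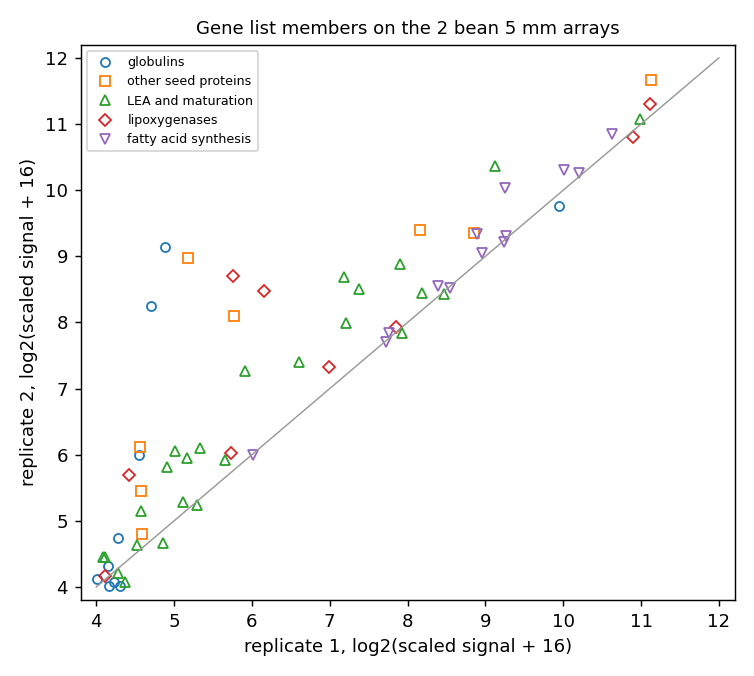
Members of 5 gene lists on the 2 bean 5 mm arrays, replicate 2 (vertical axis) against replicate 1 (horizontal axis), both as log2(scaled signal + 16), with the line of equality. At least 2-fold higher on replicate 2 were 3 of 10 members of the globulin list, 4 of 8 other seed proteins, 5 of 25 maturation genes and 3 of 9 lipoxygenases, and 0 of 13 fatty acid genes.

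In this step 6316 probe sets changed, 3125 higher and 3191 lower, and 1429 at least 2-fold, 964 higher and 465 lower. The count was 3911 and 3905 without pod elongation replicate 1 and 2, 2708 and 1641 without bean 2 mm replicate 1 and 2, 2616 and 1283 without bean 5 mm replicate 1 and 2, and 11432 and 11440 without fully grown replicate 1 and 2. The share higher was 49.5%, against 30.6% with scaling to the hybridization controls. For the values as deposited 734 probe sets were higher and 23746 lower.

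From bean 5 mm to fully grown beans, storage protein transcripts rose. GY5, a glycinin, went from below background to 17549 ± 1093, at least 2777-fold higher, and GY3 rose at least 1952-fold. BG7S-1, a basic 7S globulin, rose at least 2360-fold and CG-BETA-1, a beta-conglycinin, rose to 16267 ± 242 from 3.38, below background, and 10.6 on the bean 5 mm arrays. Of 10 members of the globulin list 9 rose (9 adjusted over the list alone), and under each other scaling too, with adjusted p = 0.000531 (camera) and adjusted p = 0.283 with an estimated correlation. The member that fell, CGS2, named after its values were seen, is a cystathionine gamma-synthase by its symbol and not a storage protein, and it lost its call without bean 5 mm replicate 1 or fully grown replicate 2.

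All 25 maturation genes rose (25 adjusted over the list alone), against 20 higher and 3 lower with scaling to the hybridization controls, with adjusted p = 5.06e-10 and adjusted p = 0.482 with an estimated correlation. PM31 rose at least 2119-fold and PM28 at least 626-fold. All 8 other seed proteins rose (8 adjusted over the list alone), against 4 higher and 1 lower with scaling to the hybridization controls, with adjusted p = 0.00183 and adjusted p = 0.543 with an estimated correlation. Without the probe sets called cross-hybridizing the adjusted p of this list was 0.0534. That setting left out the sets standing for P34 and KTI3, whose identifiers end in _a_at. SBP2, a sucrose-binding protein, rose 370-fold, from 17.8 ± 14.2 to 11972 ± 1449.

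Lipoxygenases divided, with 4 of 9 rising and 4 falling (4 and 4 adjusted over the list alone). The seed enzyme LOX1.1 rose to 16908 ± 597 from 5.42, below background, and 35.5 on the bean 5 mm arrays, and its log2 change of 8.99 was 8.36 without bean 5 mm replicate 1 and 9.63 without replicate 2. LOX7 fell 13.1-fold, from 1827 ± 84.7 to 132 ± 66.3. The list was not called (adjusted p = 0.686), and camera put it downward although its mean log2 change was 1.49. With scaling to the hybridization controls camera called it upward (adjusted p = 0.00898).

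In the same step ANR1 fell at least 120-fold, from 2075 ± 80.2 to below background, DFR2 at least 35.0-fold and ANS2 26.6-fold. CHR5 rose at least 80.3-fold, on its probe set that can match several transcripts. Of all 25 phenylpropanoid and flavonoid genes 10 rose and 7 fell (10 and 7 adjusted over the list alone), against 3 higher and 15 lower for the values as deposited and 3 higher and 21 lower with scaling to the hybridization controls. That list was not called, with adjusted p = 0.333, but had adjusted p = 0.00987 in the downward direction without cross-hybridizing probe sets. SCB1 fell 8.20-fold and LEC1-A 3.41-fold, while HPS rose 4.37-fold but was at -0.20 on the log2 scale with scaling to the hybridization controls. FAD2-1A rose 13.3-fold and SACPD-C, a stearoyl desaturase, 7.54-fold, from 1699 ± 190 to 12891 ± 1070.

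The 4 ribosomal protein genes found by symbol were called higher, by 1.70-fold to 2.52-fold. Of these, 3 were called lower after quantile normalization, 1 for the values as deposited and 4 with scaling to the hybridization controls. Of 9 sugar transport and cleavage genes 7 rose (7 adjusted over the list alone), against 5 higher and 2 lower after quantile normalization, 1 and 2 for the values as deposited, and 1 and 6 with scaling to the hybridization controls, with adjusted p = 0.312.

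**Figure D3:**
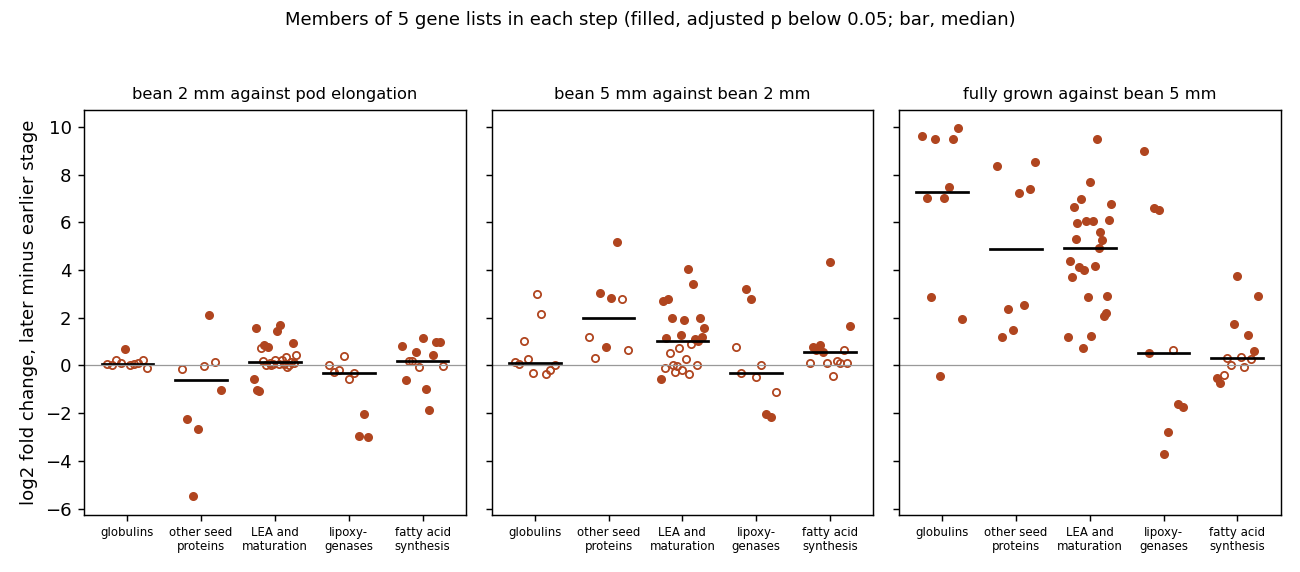
Change of each member of 5 gene lists in the 3 steps, as log2 fold change of the later over the earlier stage (vertical axis), with the list on the horizontal axis, filled points for an adjusted p below 0.05 and bars at medians. All 25 maturation genes rose in the last step (20 higher and 3 lower with scaling to the hybridization controls), as did 9 of 10 members of the globulin list, while fatty acid genes in that step were 5 higher and 2 lower, against 2 and 10 with that scaling, 3 and 9 as deposited and 4 and 4 after quantile normalization.

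**Figure D4:**
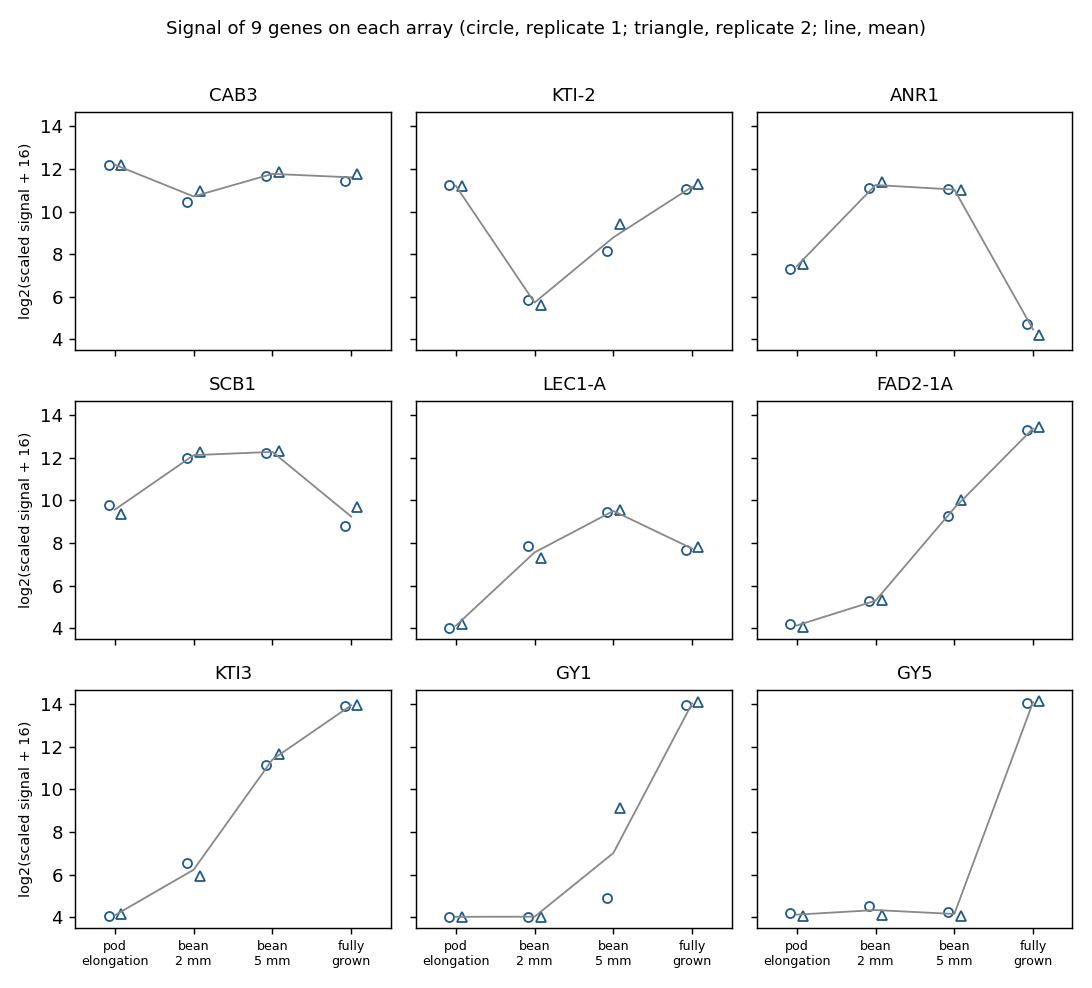
Signal of 9 genes on each array, as log2(scaled signal + 16) on the vertical axis, by stage, with circles for replicate 1, triangles for replicate 2 and lines through the means. As linear scaled signal, not on the log2 axis, GY5 had means of at most 4.41 through bean 5 mm and reached 17549 in fully grown beans. On the same linear scale ANR1 stood at 2418 and 2075 in bean 2 mm and bean 5 mm.

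In the last step 17512 probe sets changed, 10618 higher and 6894 lower, and 6988 at least 2-fold, 4038 of them higher. The share higher, 60.6%, was 49.5% after quantile normalization, 8.18% for the values as deposited and 2.12% with scaling to the hybridization controls. The median change of all tested probe sets was 0.14 on the log2 scale, against 0.00 after quantile normalization, -0.64 as deposited and -1.36 with scaling to the hybridization controls. In the first step it was 0.08, against 0.67 as deposited, and in the second -0.05, against -0.76 as deposited.

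The first and last steps shared no array but 1 estimate of spread per probe set, so overlaps are set against lists independent within 100 bins of that spread, a comparison chosen after the overlaps were seen. Of the probe sets higher in the first step, 2298 were lower in the last, against 1931, and 2966 were higher in both, against 3111. Lower in both were 1529, against 1368, and lower then higher 2039, against 2045. Over all probe sets, independent lists gave 1826, 2812, 1405 and 2163 in the same order. No excess over either is taken as a shared effect. The 4495 calls shared in direction became 2612 and 2698 without pod elongation replicate 1 and 2, and 2828 without bean 2 mm replicate 1.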

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

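The comparisons in this part were chosen after the values had been seen. Probe sets of organisms other than soybean, outside the tested ones, stood above the median tested soybean signal on all 8 arrays in 1 case for Heterodera glycines and 11 cases for Phytophthora sojae. The sucrose binding protein 3' control probe set of the array, also outside the tested ones, had a mean scaled signal of 18449.9 in fully grown beans. It was at 47.1 and 46.3 on the pod elongation arrays, 7.70 and 4.58 at bean 2 mm, and 240 and 1609 at bean 5 mm.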

How the results depend on the processing

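Scaling to the hybridization controls was chosen after the data had been seen. The values as deposited were the planned form of the analysis, and centring on array medians, listed beforehand as another form, took their place after the data had been seen. Signal over background limits dim transcripts. Where a value moved or turned, the cause was not tested. Calls for the 3 steps in order were 15428, 5738 and 17183 with the replicate number as a block, against 15755, 6316 and 17512. Deviations of same-numbered arrays correlated between -0.0481 and 0.102, so the numbers were not taken to pair arrays. With a change of at least 2-fold required, counts were 5639, 1429 and 6988. The second step had 1997 calls at an adjusted p below 0.01, 60.5% of them higher. Fitted to only its own 4 arrays, the first step had 19394 calls, the second 9698 and the last 13676. The first and second steps thus gained calls against the fit to all arrays, and the last lost calls. Replicates differed most in fully grown beans, by a median of 0.272 on the log2 scale, against 0.118 to 0.133 elsewhere, so the shared estimate of spread may favour calls in the last step. As deposited, the first step had 24420 calls and the second 24480, and 2280 were shared between the first and last. With scaling to the hybridization controls the last step had 28999.

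Leaving out 1 array, where the lone array of a stage is assumed to vary like the others, gave 10539 to 19516 calls in the first step, 1283 to 11440 in the second and 12742 to 19846 in the last, and 2612 to 6290 shared calls. The 6 called lists became 0 with an estimated correlation (camera), 3 of 30 with an unadjusted p under 0.05, and 11 as deposited. The estimate was 0.0118 for fatty acid synthesis and 0.0204 for globulins, near the 0.01 first used. Even so, the unadjusted camera p of fatty acid synthesis in the second step went from 8.908e-05 to 0.01777. That of globulins in the last step went from 7.075e-05 to 0.01883. The loss of these calls therefore cannot be put down to correlation among members alone.

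List values here are signed normal scores of the camera test. Lipoxygenases in the second step turned to 0.0679 at pseudocount 1, to 1.55 and 0.206 without bean 5 mm replicate 1 and 2, and to 1.59 as deposited, with -0.880 the lowest without 1 array. In the last step they turned to 0.282 without bean 5 mm replicate 2 (the lowest without 1 array was -1.26), 1.49 as deposited and 3.08 with the hybridization controls. Photosynthesis in the last step turned to -0.0716 after quantile normalization, -0.484 without cross-hybridizing probe sets, -0.169 without fully grown replicate 2 (the highest without 1 array was 1.07), -0.109 as deposited and -0.786 with the hybridization controls. Fatty acid synthesis turned to -0.356 after quantile normalization in the last step, and flavonoids to 0.396 without cross-hybridizing probe sets in the first. With that setting flavonoids gained a call in the last step, at -3.12 (adjusted p = 0.00987). Lipoxygenases gained an upward call in the last step with the hybridization controls, at 3.08 (adjusted p = 0.00898). As deposited, globulins turned to -0.907 and maturation genes to -0.108 in the first step. Nodule genes turned to 0.502 as deposited and 1.33 with the hybridization controls in the last.

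Log2 changes of named genes turned as follows. After quantile normalization in the last step RPS13 was at -0.37, RPS6 at -0.41 and RPL2 at -0.38. As deposited, CCR was at 0.11 in the first step, and KTI-3 at -0.17, ACCC-2 at -0.0771 and ACCB-1 at -0.0870 in the second. As deposited in the last step RPS6 was at -0.0510, RPL37 at -0.10, RPL2 at -0.49, CCR at -0.18 and SWEET13 at -0.21. With the hybridization controls in the last step RCABETA was at -0.54, PSAD at -0.86, RPS13 at -0.99, RPS6 at -1.12, RPL37 at -1.17, RPL2 at -1.56, DGAT1A at -0.23, FAD3B at -0.98, CCR at -1.20, SWEET42 at -0.61, SUT1 at -0.76, SWEET13 at -1.23, GOLS at -0.0051, AUX28 at -0.33, HPS at -0.20 and N-21 at -0.19. Of 1400 values of named genes with 1 array left out, some lost the call and 0 turned. The latter was largely fixed beforehand. Leaving out an array of a stage outside the step cannot change the log2 change. The largest rises and falls were chosen for arrays that did not overlap, so these could not turn. Without cross-hybridizing probe sets 126 of 175 results for named genes were left.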

Other observations

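The tests of carried-over RNA, of dilution, of 3' bias and of the control level as the source of the calls in the first step were chosen after the results they bear on had been seen, as were the gene families and the isoflavone synthases.

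Among 14 families tested in 3 steps (42 tests with camera), 4 were called between pod elongation and bean 2 mm, each with adjusted p = 0.719 with an estimated correlation. Of 47 WRKY transcription factors 25 fell and 7 rose (adjusted p = 0.00115, and adjusted p = 0.719 with an estimated correlation), against 20 lower and 12 higher for the values as deposited. Of 15 NAC transcription factors 12 fell (adjusted p = 0.00453), of 22 glutathione S-transferases 13 fell (adjusted p = 0.00453) and of 20 cytochrome P450 enzymes 11 fell (adjusted p = 0.0171). As deposited, the lower and higher members of these were 9 and 2, 6 and 5, and 10 and 6. Each of these 3 gave adjusted p = 0.719 with an estimated correlation, and 2 members of each rose. The number of NAC factors rising was 0 without pod elongation replicate 1 and 1 without pod elongation replicate 2 or any bean 2 mm or bean 5 mm array. That of glutathione S-transferases was 1 without pod elongation replicate 1 or 2 or bean 2 mm replicate 2, and that of P450 enzymes 6 without fully grown replicate 1 or 2. Not called were bZIP factors, with 26 of 54 higher and 4 lower (adjusted p = 0.0574), MYB factors (0.663), heat shock factors (0.940) and PHR factors (0.862).

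In the next step 4 of 8 sieve element occlusion proteins, which plug phloem, fell (adjusted p = 0.0103, and adjusted p = 0.719 with an estimated correlation), but 1 without bean 2 mm replicate 2 or bean 5 mm replicate 2. Of 54 bZIP transcription factors 16 fell and 4 rose (adjusted p = 0.0191, and adjusted p = 0.719 with an estimated correlation), but the number falling was 6 and 3 without bean 2 mm replicate 1 and 2, and 6 and 3 without bean 5 mm replicate 1 and 2. WRKY factors were also called lower (adjusted p = 0.0103, and adjusted p = 0.719 with an estimated correlation), with 10 falling and 1 rising, but 1 falling without bean 2 mm replicate 2, 5 and 1 without bean 5 mm replicate 1 and 2, and 16 without fully grown replicate 1 or 2. As deposited, the higher and lower members were 0 and 8 for sieve element proteins, 1 and 44 for bZIP and 0 and 38 for WRKY factors. The isoflavone synthases IFS1 and IFS2 rose by 4.02 and 3.42 on the log2 scale into fully grown beans.

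Some storage and maturation transcripts were brighter on bean 5 mm replicate 2, where 3 of 10 members of the globulin list, 4 of 8 other seed proteins and 5 of 25 maturation genes were at least 2-fold higher and 0 at least 2-fold lower. Fully grown RNA carried into that sample would bring its abundant transcripts at a common share of their fully grown level, but among the 20 brightest named ones the median share was 1.97% and the lowest, of GY5, 0.00479%, which argues against it. Beans further along in development may account for the difference: of the 7943 probe sets lower in fully grown beans than in bean 2 mm, 64.8% were lower on replicate 2. Of the 10530 higher ones, 61.7% were higher there, against 50.1% of those not called. Among changes of at least 2-fold, a restriction added when the test was run, the shares were 71.5% and 70.0%.

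On the scale of the hybridization controls the typical transcript was lower in fully grown beans. Against 3' bias, bean 2 mm arrays, with actin ratios above the 2.73 of fully grown replicate 1 though below the 4.80 of replicate 2, differed in median from pod elongation by -0.10 on the log2 scale. Dilution by abundant seed transcripts would keep the summed signal level, and that sum was 0.318 of bean 5 mm, which argues against it unless the brightest signals were saturated. The 100 brightest soybean probe sets held 14.8% and 14.5% of the soybean signal on the fully grown arrays, against 4.83% to 5.93% on the others. Such a larger share goes with dilution. The highest signal over the controls differed by 1.39-fold among all arrays, as a ceiling could bring about, while 66 and 70 probe sets lay above 50% of the highest on the fully grown arrays, against 98 to 157 on the others, so saturation was left open. A difference in RNA content between stages was not tested.

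The control level separated pod elongation and bean 5 mm from the other stages. The actin 3' to 5' ratio divided the arrays the same way, at 2.05 to 2.22 against 2.73 to 4.80. So did a GAPDH 3' to middle ratio, at 1.21 to 1.31 against 1.82 to 2.04. The control level and these ratios cannot be told apart here. As the main source of the calls in the first step, the control level would leave far fewer calls for bean 5 mm against pod elongation, with like controls, than for bean 5 mm against bean 2 mm. There were 13445 against 6316. Bean 5 mm against pod elongation also skips a stage and crosses both labelled divisions, so many calls could arise there whatever the control level did. The counts alone therefore cannot decide. Of the 15755 calls of the first step, 62.9% were also called in the same direction in that comparison, which shares the pod elongation arrays. Of the 2586 probe sets called in all 3 steps, 43.5% alternated in direction, between the shares set beforehand for and against an origin in the control level. The steps share arrays, which raises that share, so this part stays open.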
